A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

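Total RNA of 4 budding yeast strains was measured on 10 single-colour Affymetrix arrays. The strains were the wild type W303-1A (WT, 3 arrays) and its derivatives lacking HPR1 (hpr1del, 3 arrays), SUB2 (sub2del, 2 arrays) or THO2 (tho2del, 2 arrays). Per the labels' protocols, cells came from mid-log cultures in YPAD, a rich medium with adenine, and biotin-labelled cRNA was made with the array maker's 1-cycle protocol. The labels call the arrays of a strain biological replicates, without saying whether the cultures were grown side by side, so p-values measure the spread between these arrays.

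The values used were those of the authors' deposited table, 1 intensity per probe set and array on a linear scale, from 1 to 35972. Software, background correction, summarisation and scaling are not given in the sources used here. The quartiles were much alike on the 10 arrays, with medians from 1346 in sub2del replicate 1 to 1541 in WT replicate 2, as is usual of intensities scaled to a shared level, though whether the authors did so is not stated. Scanner files were not used here, so signal over background was unknown, and the number of arrays limits the precision. Of 57160 cells, 3220 (5.63%) were empty for a reason that is not stated. Between 7 and 12 cells were empty on each hpr1del array, 66 in WT replicate 1 and 38 in WT replicate 3. In WT replicate 2 there were 414, and on the sub2del and tho2del arrays between 479 and 811. Probe sets empty on all 4 sub2del and tho2del arrays had a median intensity of 977.5 where filled, against 1722 for those filled on all 4, so the empty cells were not only those of dim probe sets.

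Of 5716 probe sets, 5498 had 1 gene in the platform annotation, 0 had several and 218 had no gene there. Symbols were updated through gene identifiers to the R64 gene table, which changed 12 of them. The named probe sets stood for 5449 genes, of which 47 had over 1 probe set. Between 11 and 14 of these genes, depending on the mutant, had probe sets that differed in their call. Of the named probe sets, 128 are of the kinds that can bind transcripts of several genes, and values of such paralogs are uncertain. No genome sequence was used here, so a planned relation to GC content and a planned list of genes with introns were not run. Coordinates are not printed, because the build behind the array is not stated.

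Intensities were put on the log2 scale after an offset of 16 was added, so that fold changes are those of (intensity + 16) and understate changes of dim genes. The plan had assumed log2 values and held this step for linear ones. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean per strain, all 10 arrays sharing 1 estimate of the spread, and empirical Bayes moderation. An empty cell left out its own array only, and a probe set was tested where each strain compared had at least 2 values, a rule set after the empty cells were seen. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called under 0.05. Errors given with log2 changes are standard errors (SE), and those with intensities are standard deviations (SD). WT arrays were the most variable (mean within-strain SD of 0.28 on the log2 scale, against 0.10 in hpr1del, 0.15 in sub2del and 0.14 in tho2del). A pooled spread therefore understates the error of the WT mean and overstates that of comparisons between mutants.

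Apart from the additions named below, the tests, their alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The rule took, for each mutant against WT, the 10 highest and 10 lowest log2 changes among called probe sets whose mutant arrays all lay beyond all WT arrays, and 5 of each for the other comparisons. It also took up to 4 members with the lowest adjusted p in each list described, and always 8 genes of or near the complex. Genes named outside this rule are marked as such. Lists were tested with camera at a preset correlation of 0.01 on moderated statistics, with 1 probe set per gene. The planned list of Ty elements had 0 measured members, so 31 lists were tested. The list of the respiratory chain and ATP synthase also holds genes of the citric acid cycle. Counts and medians given below for respiratory chain genes include them, and they were not tested apart. With the correlation estimated from the residuals of the arrays, camera called 0 lists in each of the 6 comparisons, and the smallest adjusted p was 0.0764. At an unadjusted p under 0.05 it had 4, 3 and 6 lists in hpr1del, sub2del and tho2del against WT, 5 for the mean of the mutants, 0 for sub2del against the other mutants and 2 for tho2del against hpr1del. The rotation test fry was run on probe sets with 10 values. It called 18, 22 and 21 lists in hpr1del, sub2del and tho2del against WT on balance of direction, and all 31 in each for change in either direction.

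Because the mutants were compared with the same WT arrays, 100 simulations of unchanged strains that share simulated WT arrays gave an overlap, correlation and covariance with no effect. All 10 arrays were simulated with genes varying independently, and no real WT array entered. A shift of many genes in the WT cultures could not arise there, so its part in the overlap was not measured. The WT arrays were too few to be split into parts of 2. Coding length came from the R64 gene table and spans introns. Permutation tests used 100000 resamples and were two-sided. Alternatives were other scalings, filters, variance models, thresholds, a replicate block and leaving out each array. Added after seeing the data were the list tests of tho2del against hpr1del and of the mean of the mutants against WT, at least 1 value per strain, only probe sets with 10 values, log2 with no offset, a comparison of sub2del with tho2del alone, and a block of 2 levels for the 5 arrays with over 5% empty cells (sub2del, tho2del, WT replicate 2) and the 5 with fewer. The last is called the empty-cell block, and the labels give no batch. Since hpr1del lies in 1 level and sub2del and tho2del in the other, it compares hpr1del with WT replicates 1 and 3, and sub2del and tho2del with WT replicate 2.

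The fit was tested on simulated data with 200 changed genes. For hpr1del against WT, over 5450 probe sets, it recovered 56.9%, 90.8% and 98.6% of genes changed by 0.5, 1 and 2 on the log2 scale, and 4.62% of its calls were false. For sub2del, over 4632 probe sets, it recovered 45.1%, 96.2% and 100%, with 4.38% false. For tho2del, over 4576 probe sets, the values were 63.5%, 98.3% and 97.5%, with 4.92% false. In these simulations all strains varied alike and genes varied independently, whereas the real WT arrays varied more than the others. The simulations therefore do not give the share of false calls in the data.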

Results

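THO/TREX is a conserved complex that couples transcription elongation to the export of mRNA from the nucleus. HPR1 and THO2 encode core subunits of its THO part, and SUB2 encodes an RNA helicase that joins it. The series asked how gene expression differs from wild type in yeast strains that lack each of these subunits. The data were 10 arrays of W303-1A (WT, n = 3), hpr1del (n = 3), sub2del (n = 2) and tho2del (n = 2). Arrays of a mutant lay close together, with an SD of the log2 difference between 0.09 and 0.17 in hpr1del, 0.21 in sub2del and 0.20 in tho2del. WT arrays lay between 0.30 and 0.48 apart.

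Each deleted gene had its lowest level in its own strain. HPR1 read 202 ± 12.3 (SD, n = 3) in hpr1del against 573 ± 56.4 (n = 3) in WT, a log2 change of -1.43 ± 0.08 (SE, limma adjusted p = 1.24e-05). THO2 read 252 ± 98.0 (n = 2) in tho2del against 2467 ± 97.5 in WT, a log2 change of -3.26 ± 0.19 (limma adjusted p = 5.25e-06). SUB2 read 79.2 ± 34.8 (n = 2) in sub2del against 12370 ± 365 in WT, a log2 change of -7.07 ± 0.18 (limma adjusted p = 2.43e-07). The drop of HPR1 was the smallest of these, and where its probes lie relative to the deletion was not analysed here. THO2 also fell in the strains that keep the gene, to 1382 ± 64.9 in hpr1del and 1186 ± 99.6 in sub2del (limma adjusted p = 0.00392 and 0.00116).

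Other genes of the complex moved by less. MFT1, a THO subunit, rose in all 3 mutants, from 853 ± 48.3 in WT to 1090 ± 10.8 in hpr1del, 1573 ± 147 in sub2del and 1590 ± 38.9 in tho2del. YRA1, an mRNA export adaptor, rose from 7658 ± 710 to between 10400 and 11650 in the mutants. TEX1 fell in sub2del and tho2del (log2 -0.45 and -0.47), and in hpr1del its log2 difference was 0.05 (limma adjusted p = 0.731). Its call in sub2del was lost after quantile normalization (-0.30), after subtracting array medians (-0.26) and without sub2del replicate 2 (-0.42). In tho2del it was lost without tho2del replicate 2 (-0.29) and with only the arrays compared (-0.47, limma adjusted p = 0.0541). THP2 lay near the threshold in hpr1del (limma adjusted p = 0.0498), tho2del (0.0457) and not past it in sub2del (0.877), and both calls were lost without single arrays, the highest limma adjusted p being 0.149 in hpr1del without hpr1del replicate 3 and 0.317 in tho2del without tho2del replicate 1. The call in hpr1del was also lost after quantile normalization (-0.102, limma adjusted p = 0.380), and both after array medians were subtracted (-0.147 and 0.142 in hpr1del, -0.108 and 0.294 in tho2del). The list of 25 genes of THO/TREX and mRNA export, which holds the deleted genes, did not pass with camera (adjusted p = 0.885, 0.361 and 0.151 in hpr1del, sub2del and tho2del). Of its tested genes 7 rose and 7 fell in hpr1del, 8 and 7 in sub2del and 9 and 6 in tho2del. The test fry placed it downward in sub2del (adjusted p = 0.00780) and upward in tho2del (0.00172). The call in sub2del includes the deleted SUB2 itself (log2 -7.07), while the list's median there was 0.0244. Since fry was not run without the deleted genes, that call does not show a fall of the other members. HIS3, which replaces SUB2 in sub2del and is a mutant allele in all 4 strains per the labels, read 2282 ± 879 in WT, with arrays from 1358 to 3109. It read 503 ± 7.40 in hpr1del, 347 ± 38.0 in sub2del and 498 ± 3.41 in tho2del. The labelled genotypes alone do not account for a level that was highest in WT and lowest in the strain with the HIS3 marker. Amino acid synthesis genes, a list without HIS3, also fell in all 3 mutants (medians -0.622, -0.995 and -0.961 in hpr1del, sub2del and tho2del). On the WT arrays their medians ranked as HIS3 did, at -0.29, 0.241 and 0.0635 in replicates 1, 2 and 3, but 3 arrays can rank alike by chance. The log2 changes of HIS3 (-2.066, -2.585 and -2.082) were larger than the list medians, so the fall of the list does not account for them. The level of HIS3 does not show by itself whether the WT strain is mislabelled. Whether that strain is as labelled bears on every comparison with WT, and no test here resolves it.

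**Figure D1:**
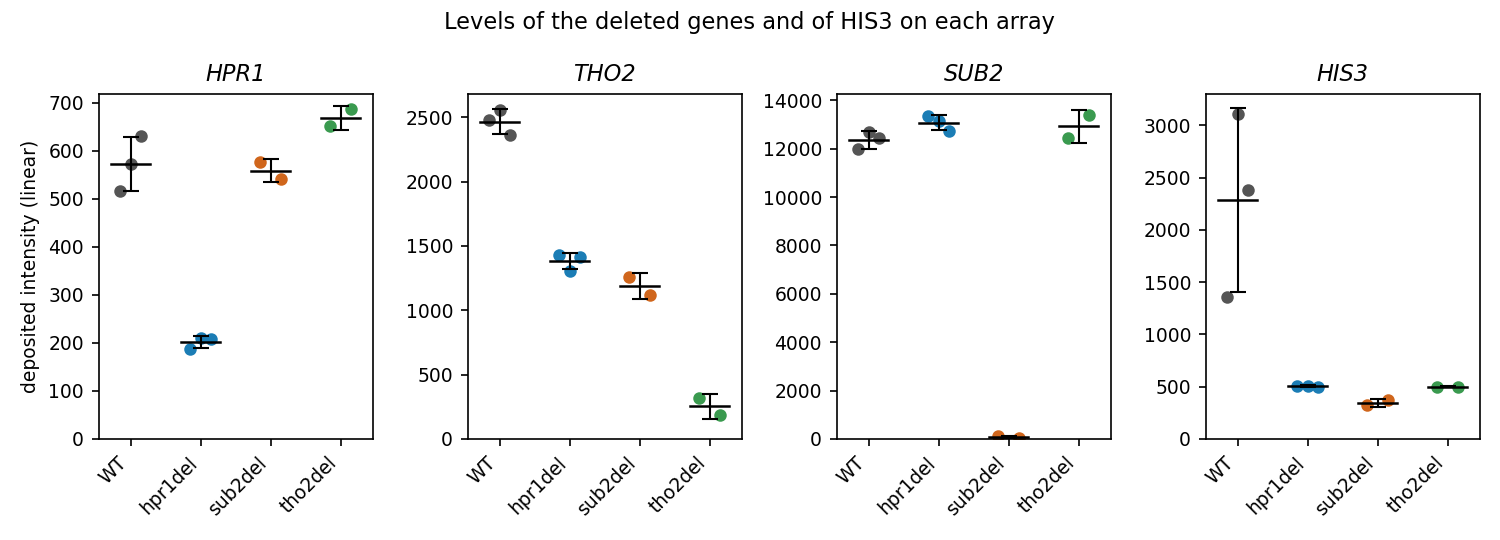
Deposited linear intensity of HPR1, THO2, SUB2 and HIS3 on each array (points), by strain, with the strain mean (bar) and SD (whiskers). SUB2 lies between 54.6 and 104 in sub2del and at 11974 or above on the other arrays, and THO2 is at an intermediate level in hpr1del and sub2del.

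The comparison of hpr1del with WT asks what loss of the THO subunit Hpr1 changes. Amino acid synthesis, iron uptake and ergosterol genes fell in hpr1del, and G1/S, G2/M, proteasome, respiratory chain and DNA damage genes rose. These are lists called with camera at the preset correlation, and each call was lost with an estimated correlation (adjusted p from 0.0995 to 0.704). Of 28 M/G1 genes, the other cell cycle list, 10 rose and 10 fell (median -0.02, camera adjusted p = 0.837; fry adjusted p = 0.0291, downward; median 0.0303 after quantile normalization). Among single genes, OYE3, an NADPH oxidoreductase, was 8.58-fold higher (294 ± 43.8 in WT, 2654 ± 438 in hpr1del, n = 3 each). SPO19, a sporulation gene, was 6.98-fold higher (27.9 ± 4.29 in WT, near the offset of 16, and 289 ± 9.24 in hpr1del), GIT1, a glycerophosphoinositol permease, 4.90-fold, GPH1, glycogen phosphorylase, 4.27-fold, and CWP1, a cell wall mannoprotein, 4.17-fold. CRG1, a methyltransferase gene, was 5.69-fold higher, SRT1 4.53-fold, HMS1 4.45-fold and YDR042C 7.48-fold. CDA1, a chitin deacetylase of the spore wall, read 118 ± 4.24 in hpr1del and 13.1 ± 5.38 in WT (n = 2 each), under the offset, so no fold is given. RSB1, which codes for a sphingoid base transporter, was 11.9-fold lower, FRE4, a ferric reductase gene, 9.63-fold, and HXT1, a low-affinity glucose transporter gene, 9.24-fold (12166 ± 1731 in WT, 1300 ± 162 in hpr1del). FIT2 and FIT3, cell wall proteins that help take up iron, were 8.43-fold and 6.80-fold lower, and MIG3 was 7.57-fold lower. YJL213W, YHR140W, BSC5 and TMT1 were between 5.99-fold and 8.96-fold lower. Of the genes above, GPH1, RSB1, FRE4, MIG3, YJL213W and TMT1 also had only 2 WT values, with the other WT cell empty.

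By list, 45 of 60 tested genes of amino acid synthesis fell in hpr1del and 3 rose (47 and 4 adjusted over the list alone), with a median log2 change of -0.62. The list mixes synthesis genes of several pathways with GCN4, which encodes an activator of such genes. Which members Gcn4 controls was not analysed, so the fall does not measure its activity. A further 9 of the 69 genes of this list on the array could not be tested because WT had at most 1 value, although hpr1del had 3. They made up 9 of the 48 named probe sets untested in this comparison, so empty WT cells were not spread evenly over genes. Camera gave an adjusted p = 6.06e-10 for this list, and adjusted p = 0.634 with an estimated correlation. ARG1, an arginine synthesis gene, fell by 2.27 ± 0.14 on the log2 scale, ARG8 by 1.85 ± 0.14, MET2 by 1.36 ± 0.10 and ARO3 by 1.12 ± 0.07. Of 28 iron regulon genes, 21 fell and 2 rose (24 and 2 adjusted over the list alone; median -1.17, camera adjusted p = 1.14e-07, and adjusted p = 0.474 with an estimated correlation), among them ARN2, a siderophore transporter gene (-1.95 ± 0.11), and SMF3 (-1.36 ± 0.09). Of 26 ergosterol genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.46, camera adjusted p = 0.000174, and adjusted p = 0.704 with an estimated correlation), with ERG3 at -1.36 ± 0.10 and ERG26 at -1.10 ± 0.10.

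Of 36 genes of the G1/S transition, 27 rose and 0 fell in hpr1del (29 and 0 adjusted over the list alone), with a median of 0.61. Camera gave an adjusted p = 1.43e-09 for them, and adjusted p = 0.194 with an estimated correlation. PCL1, a G1 cyclin gene, rose by 1.77 ± 0.16 and CDC45, a replication initiation gene, by 1.06 ± 0.07. Of 23 G2/M genes, 16 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.63, camera adjusted p = 4.85e-05, and adjusted p = 0.385 with an estimated correlation), among them SPO12 (1.43 ± 0.08) and CLB4, a B-type cyclin gene (0.94 ± 0.07). Proteasome genes rose in 30 of 37 cases and fell in 0 (30 and 0 adjusted over the list alone; median 0.37, camera adjusted p = 2.34e-09, and adjusted p = 0.194 with an estimated correlation). RPN4, which encodes the activator of proteasome genes, rose by 1.05 ± 0.11. Of 48 genes of the respiratory chain and ATP synthase list, 34 rose and 0 fell (34 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 1.97e-08, and adjusted p = 0.513 with an estimated correlation), COX7 by 0.93 ± 0.10. Of 30 DNA damage response genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.36, camera adjusted p = 5.20e-05, and adjusted p = 0.0995 with an estimated correlation). The checkpoint kinase genes DUN1 (1.16 ± 0.08) and RAD53 (0.67 ± 0.06) were among them, as was HUG1 (0.96 ± 0.10). Cell wall integrity genes rose in 17 of 25 cases and fell in 2 (18 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 6.50e-05, and adjusted p = 0.194 with an estimated correlation), with the MAP kinase gene SLT2 at 0.85 ± 0.07.

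A further 5 lists passed in hpr1del by less. They were ribosome biogenesis (median 0.11, camera adjusted p = 0.00855), the general stress response (0.37, 0.0139), meiosis and sporulation (0.26, 0.0240), aminoacyl-tRNA synthetases (-0.16, 0.0269) and the spliceosome (0.14, 0.0442). With an estimated correlation their adjusted p lay between 0.704 and 0.801. The general stress call was lost without WT replicate 2 (median 0.11, adjusted p = 0.324) and without WT replicate 3 (0.11, adjusted p = 0.401). WT replicate 1 stood apart in that list, 0.93 above the mean of the other WT arrays. That call (adjusted p = 0.0536) and the spliceosome call (0.0536) were also lost without the dimmest 25% of probe sets, and those of meiosis (0.0578), spliceosome (0.0614) and synthetases (0.0886) after quantile normalization. Meiosis (0.0519) and synthetases (0.0626) were also lost after array medians were subtracted. The other 4 calls were each lost in leaving out arrays, ribosome biogenesis without WT replicate 1 (adjusted p = 0.242), meiosis without WT replicate 1 (0.135) or 3 (0.232), synthetases without WT replicate 2 (0.0635), and spliceosome without WT replicate 1 (0.291) or 3 (0.0772) or hpr1del replicate 1 (0.0635). The spliceosome call was lost with the replicate block too (0.0548). With fry the lists of ribosome biogenesis (0.0521), general stress (0.353), meiosis (0.287) and the spliceosome (0.0851) did not pass.

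In all, 2497 of 5450 probe sets passed in hpr1del, 1255 higher and 1242 lower, of which 168 and 212 changed at least 2-fold. Calls were 50.3% higher as deposited, 59.1% after quantile normalization and 57.8% after subtracting array medians. With the empty-cell block 2564 passed. The synthetase call was lost with it (adjusted p = 0.0597), the general stress median was 0.182 (adjusted p = 0.0424), and the medians of the iron and respiratory lists were -0.965 and 0.415. With array weights 4149 passed. Weights were 0.106 for WT replicate 1, 0.216 for WT replicate 2 and 6.45 for WT replicate 3.

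The comparison of sub2del with WT asks the same of the helicase Sub2. Amino acid, iron, ergosterol, purine and respiratory chain genes fell, and proteasome, G1/S and G2/M genes rose. Each of these list calls was lost with an estimated correlation (adjusted p from 0.372 to 0.654). Of 26 M/G1 genes, 10 rose and 12 fell (median -0.04, camera adjusted p = 0.696; median 0.0651 after quantile normalization). CHM7, an ESCRT-related gene of the nuclear envelope, was 13.7-fold higher (384 ± 43.9 in WT, n = 3, and 5446 ± 164 in sub2del, n = 2). ARO10, which encodes a phenylpyruvate decarboxylase, was 12.7-fold higher and BIO2, biotin synthase, 11.8-fold. NDC80, a kinetochore gene, was 7.99-fold higher, KAR1, a spindle pole body gene, 7.22-fold, TDA4 5.80-fold and MAL32, a maltase gene, 5.57-fold. The MAL32 probe set had 2 WT values and is of a kind that can bind transcripts of several genes, so its signal may not be that of MAL32 alone. BRN1, a condensin gene, read 139 ± 55.8 in sub2del and 8.22 ± 5.105 in WT (n = 2 each), under the offset, so no fold is given. IZH4 was 17.6-fold higher, but its WT arrays varied widely (1152 ± 1497), as did those of TIP1 (4570 ± 3374, 5.44-fold higher). CHA1, a serine and threonine deaminase gene, was 17.3-fold lower (2504 ± 197 in WT, 130 ± 8.96 in sub2del). RSB1 was 17.2-fold lower, FIT2 15.8-fold, BSC1 13.7-fold, CTR1, a copper transporter gene, 13.1-fold, ICY1 12.2-fold, and FET3, the oxidase of high-affinity iron uptake, 12.1-fold. PUT4, a proline permease gene, was 11.9-fold lower, FRE1, a ferric and cupric reductase gene, 11.5-fold, and BNA1, of NAD synthesis, 11.0-fold. RSB1 and BNA1 had only 2 WT values.

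In sub2del 47 of 56 amino acid synthesis genes fell and 3 rose (48 and 3 adjusted over the list alone; median -0.995, camera adjusted p = 2.94e-07, and adjusted p = 0.654 with an estimated correlation), MET6, methionine synthase, by 3.13 ± 0.19. Of 23 iron regulon genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone; median -1.72, camera adjusted p = 2.09e-05, and adjusted p = 0.631 with an estimated correlation). Of 25 ergosterol genes, 22 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.98, camera adjusted p = 1.22e-05, and adjusted p = 0.631 with an estimated correlation), among them ERG26 (-2.58 ± 0.11) and ERG28 (-1.88 ± 0.11). Purine and one-carbon genes fell in 16 of 21 cases and rose in 1 (16 and 1 adjusted over the list alone; median -0.91, camera adjusted p = 0.00201, and adjusted p = 0.650 with an estimated correlation), ADE17 by 2.90 ± 0.14 and ADE8 by 2.05 ± 0.15. Respiratory chain genes fell in 33 of 47 cases and rose in 0 (33 and 1 adjusted over the list alone; median -0.58, camera adjusted p = 0.000360, and adjusted p = 0.654 with an estimated correlation). RIP1, the Rieske iron-sulfur subunit, fell by 1.86 ± 0.09 and CYT1, cytochrome c1, by 1.43 ± 0.10. Of 18 aminoacyl-tRNA synthetase genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 0.0140, and adjusted p = 0.654 with an estimated correlation), DPS1 by 1.05 ± 0.09.

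Proteasome genes rose in 27 of 33 cases in sub2del and fell in 1 (27 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 6.96e-12, and adjusted p = 0.372 with an estimated correlation), RPN11 by 1.23 ± 0.09. Of 21 G2/M genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.74), and of 33 G1/S genes, 22 rose and 4 fell (22 and 4 adjusted over the list alone; median 0.59). Camera gave adjusted p = 4.21e-07 and 1.20e-06 for them, and adjusted p = 0.425 for each with an estimated correlation. ASF1, a histone chaperone gene, rose by 1.49 ± 0.08, SWE1, a cell cycle kinase gene, by 1.47 ± 0.09, and BUD4 by 1.58 ± 0.13. Ribosome biogenesis genes rose in 31 of 75 cases and fell in 12 (31 and 12 adjusted over the list alone; median 0.17, camera adjusted p = 3.28e-05, and adjusted p = 0.654 with an estimated correlation), NOP16 by 2.18 ± 0.07. Cell wall integrity genes passed narrowly (median 0.19, camera adjusted p = 0.0274, and adjusted p = 0.631 with an estimated correlation), and not without sub2del replicate 2 (median 0.10, adjusted p = 0.0561) or with the empty-cell block (0.15, adjusted p = 0.0550).

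In sub2del 2834 of 4632 probe sets passed, 970 higher and 1864 lower, and 239 and 547 of them changed at least 2-fold. The median log2 change over all probe sets was -0.16, so the balance of directions depended on the scaling. Calls were 34.2% higher as deposited, 43.6% after quantile normalization and 52.3% after subtracting array medians, which moved the median to 0.03. The sign of the median of each list past the threshold held in both scalings. General stress genes, of which 24 fell and 1 rose (median -0.558), missed the threshold as deposited (camera adjusted p = 0.0889) and passed after quantile normalization (-0.475, 0.0423) and after array medians were subtracted (-0.371, 0.0146). The spliceosome (median 0.0713, 0.0614) passed in these scalings too (0.168, 0.0179 and 0.261, 0.0370). With the empty-cell block 2546 passed, and the medians of the iron and respiratory lists were -1.89 and -0.60.

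The comparison of tho2del with WT asks what loss of Tho2 changes. The falls of amino acid, iron, ergosterol, purine and respiratory chain genes and the rises of proteasome, G1/S and G2/M genes were seen here too, as was the rise of ribosome biogenesis genes found in sub2del. Phosphate genes also fell. Each of these list calls was lost with an estimated correlation (adjusted p from 0.229 to 0.559). Of 26 M/G1 genes, 12 rose and 9 fell (median 0.16, camera adjusted p = 0.543). BIO2 was 9.66-fold higher, ARO10 8.57-fold, CHM7 7.98-fold and KAR1 7.83-fold. SPS4, a sporulation gene, was 8.39-fold higher (47.0 ± 8.48 in WT, n = 3, and 510 ± 28 in tho2del, n = 2), MFA1, which encodes the mating pheromone a-factor, 6.38-fold, NOP16 5.63-fold, KRE28 5.47-fold, RIM4, a meiotic RNA-binding protein gene, 5.40-fold, and IZH4 17.1-fold against the same variable WT arrays. PHO84, the high-affinity phosphate transporter gene, was 13.7-fold lower (13474 ± 3231 in WT, 956 ± 146 in tho2del). FIT2 was 12.1-fold lower, YHR140W 11.9-fold, RSB1 10.7-fold, BNA1 10.4-fold (2 WT values for each of these last 2), FET3 9.69-fold, CTR1 9.65-fold, BSC1 9.63-fold, PUT4 9.28-fold and ICY1 8.60-fold.

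In tho2del 53 of 57 amino acid synthesis genes fell and 2 rose (53 and 2 adjusted over the list alone; median -0.96, camera adjusted p = 2.65e-10, and adjusted p = 0.423 with an estimated correlation), MET17 by 2.75 ± 0.19. Of 24 iron regulon genes, 22 fell and 0 rose (23 and 0 adjusted over the list alone; median -1.26, camera adjusted p = 1.26e-06, and adjusted p = 0.409 with an estimated correlation). Of 24 ergosterol genes, 21 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.89, camera adjusted p = 2.02e-07, and adjusted p = 0.409 with an estimated correlation), with HMG1, HMG-CoA reductase, at -1.59 ± 0.11. Of 22 purine genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.62, camera adjusted p = 0.000306, and adjusted p = 0.409 with an estimated correlation). Respiratory chain genes fell in 28 of 48 cases and rose in 0 (28 and 0 adjusted over the list alone; median -0.46, camera adjusted p = 7.95e-05, and adjusted p = 0.559 with an estimated correlation), RIP1 by 1.55 ± 0.09. Phosphate regulon genes fell in 11 of 15 cases and rose in 1 (11 and 1 adjusted over the list alone; median -0.69, camera adjusted p = 0.00881, and adjusted p = 0.229 with an estimated correlation). SPL2 fell by 1.96 ± 0.14, and PHO3, an acid phosphatase gene, rose by 1.19 ± 0.12. In sub2del 10 of 12 phosphate genes fell and 2 rose (median -0.413), and the list passed with fry (adjusted p = 5.42e-05) and not with camera (adjusted p = 0.241).

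Of 76 ribosome biogenesis genes, 47 rose and 4 fell in tho2del (51 and 4 adjusted over the list alone; median 0.36, camera adjusted p = 1.27e-08, and adjusted p = 0.409 with an estimated correlation), NOP8 by 1.85 ± 0.15. Proteasome genes rose in 26 of 35 cases and fell in 0 (26 and 0 adjusted over the list alone; median 0.35), G2/M genes in 19 of 22 with 0 falling (19 and 0 adjusted over the list alone; median 0.74) and G1/S genes in 22 of 34 with 2 falling (23 and 2 adjusted over the list alone; median 0.54). Camera gave adjusted p = 6.74e-08, 1.89e-07 and 1.26e-06 for them, and adjusted p = 0.229 for each with an estimated correlation. CDC45 rose by 1.75 ± 0.08 and SPO12 by 1.78 ± 0.08. Cell wall integrity genes rose in 15 of 24 cases and fell in 3 (15 and 3 adjusted over the list alone; median 0.33, camera adjusted p = 0.00263, and adjusted p = 0.229 with an estimated correlation), PRM5 by 1.44 ± 0.11. Pheromone-induced genes (median 0.58, camera adjusted p = 0.0132), the DNA damage response (0.22, 0.0354), meiosis and sporulation (0.46, 0.00562), the spliceosome (0.15, 0.0133) and aminoacyl-tRNA synthetases (-0.22, 0.0239) passed as well, and had adjusted p between 0.229 and 0.609 with an estimated correlation. KAR5, a nuclear fusion gene, rose by 1.91 ± 0.11 and HUG1 by 1.49 ± 0.11. The meiosis list was lost, with a median of -0.01, after quantile normalization (adjusted p = 0.124), with the empty-cell block (0.22, adjusted p = 0.158) and with fry (adjusted p = 0.0826), and 30 of its 53 genes had too few values to be tested. The DNA damage call was lost without tho2del replicate 2 (adjusted p = 0.0688), without WT replicate 3 (0.0675), with the block (0.0532), after quantile normalization (0.113) and without the dimmest 25% of probe sets (0.402), and the spliceosome call without WT replicate 1 (0.0805) and with the block (0.148). The pheromone call was lost after quantile normalization (0.0712) and without the dimmest 25% (0.0782), and the synthetase call after quantile normalization (0.200) and after array medians were subtracted (0.0907).

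In tho2del 2634 of 4576 probe sets passed, 1133 higher and 1501 lower, and 220 and 384 changed at least 2-fold. Calls were 43.0% higher as deposited, 41.3% after quantile normalization and 53.4% after subtracting array medians. With the empty-cell block 2297 passed, and the medians of the iron and respiratory lists were -1.57 and -0.41.

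**Figure D2:**
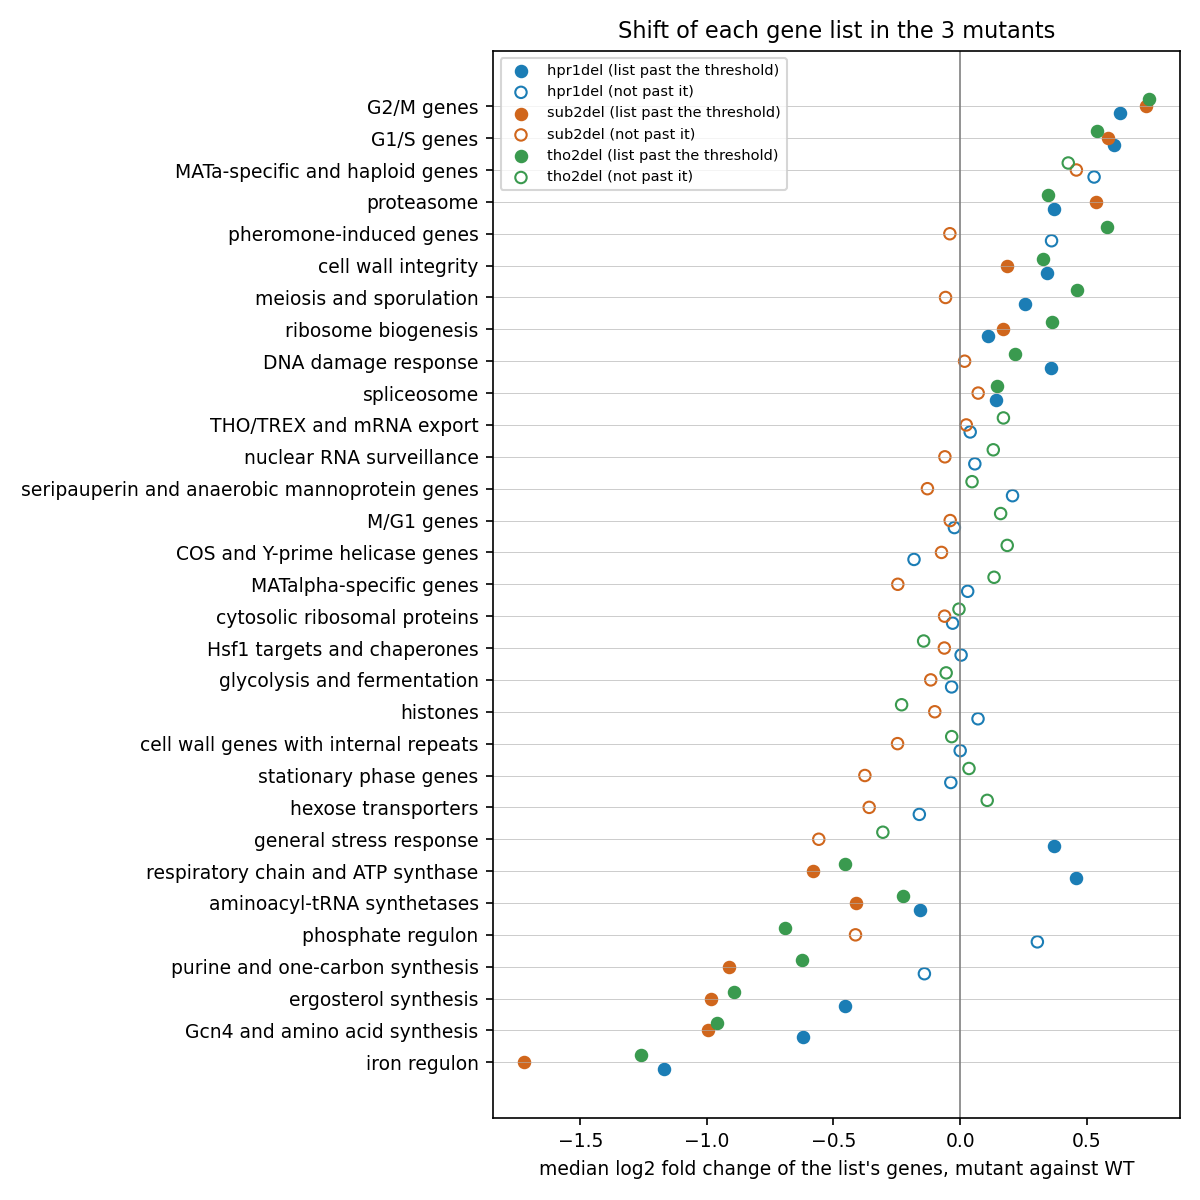
Median log2 fold change against WT of the tested genes of each of 31 lists in hpr1del, sub2del and tho2del, with filled points where camera at the preset correlation passed an adjusted p of 0.05 and open points elsewhere. Iron regulon medians lie at -1.17, -1.72 and -1.26, and the respiratory chain list at 0.46 in hpr1del but -0.58 and -0.46 in sub2del and tho2del.

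The mutants were set against each other to ask how much of the response they share. Over the 4306 probe sets tested in all 3, 441 were higher and 748 lower in every mutant. Independent lists would share 45.6 and 147. Simulated unchanged strains with simulated WT arrays in common shared 0.07 on average, in a setting where no shift of many WT genes could arise. CHM7 (3.58-fold in hpr1del, 13.7-fold in sub2del, 7.98-fold in tho2del), BIO2, ARO10, KAR1 and CRG1 rose furthest on average, and RSB1 (11.9-fold, 17.2-fold and 10.7-fold lower), FIT2, YHR140W, BSC1 and BNA1 fell furthest. RSB1 and BNA1 rest on 2 WT values. Pairs shared 1943 calls of the same direction for sub2del and tho2del, 1401 for hpr1del and tho2del and 1329 for hpr1del and sub2del, with 49, 93 and 145 called in opposite directions. The independent lists of these pairs would share 220, 217 and 187 higher and 591, 357 and 443 lower calls.

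**Figure D3:**
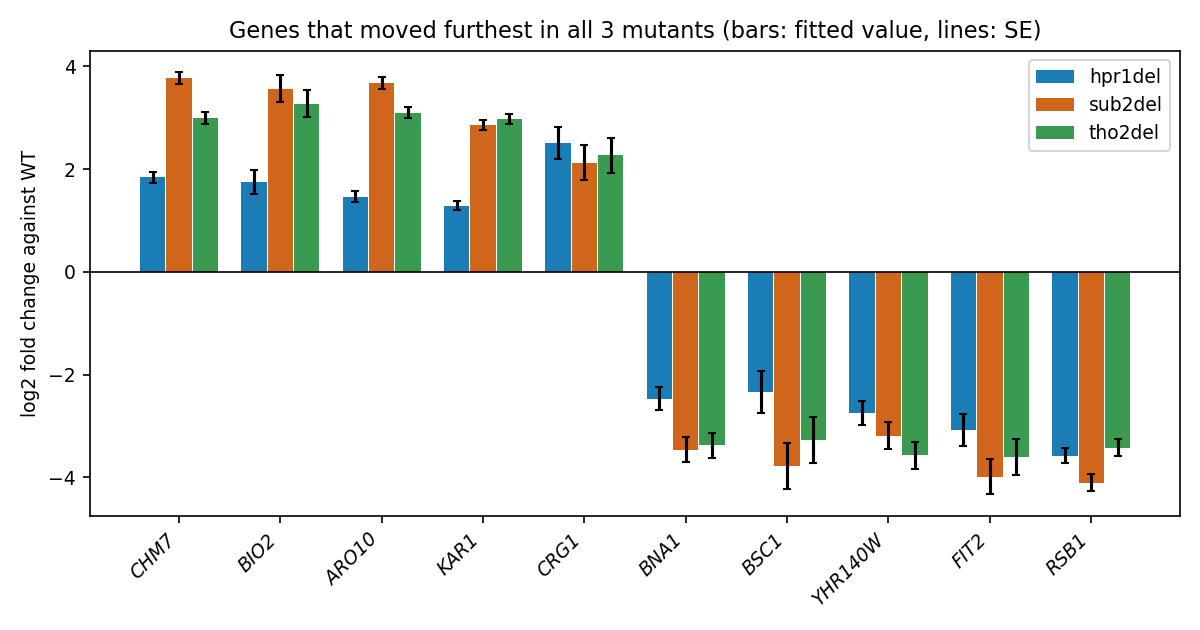
Log2 fold change against WT (bars) with its SE (lines) in the 3 mutants for the 5 genes that rose and the 5 that fell furthest on average among those called in all 3. KAR1 stands at 1.29 in hpr1del and at 2.85 and 2.97 in sub2del and tho2del.

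Across genes, which are not independent replicates, fold changes correlated at r = 0.87 for sub2del and tho2del, 0.72 for hpr1del and tho2del and 0.65 for hpr1del and sub2del. Simulated unchanged strains with simulated WT arrays in common gave 0.72, 0.82 and 0.79. The covariance was 0.475, 0.271 and 0.268, against 0.0230, 0.0231 and 0.0230 in simulation. The WT arrays could not be split, so part of the overlap may come from them. For the mean of the 3 mutants against WT, 2668 of 4306 probe sets passed, 1048 higher and 1620 lower, and 39.3% of calls were higher as deposited, 45.5% after quantile normalization and 53.2% after subtracting array medians.

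The comparison of sub2del with the mean of hpr1del and tho2del asks whether loss of the helicase differs from loss of the THO core. Respiratory chain genes were lower in sub2del, with 31 of 47 falling and 0 rising (33 and 0 adjusted over the list alone; median -0.60, camera adjusted p = 3.59e-06, and adjusted p = 0.889 with an estimated correlation), RIP1 by 1.28 ± 0.08. General stress genes were lower too, 24 of 42 against 0 (26 and 0 adjusted over the list alone; median -0.70, camera adjusted p = 0.000550, and adjusted p = 0.889 with an estimated correlation), with RTC3 at -1.33 ± 0.07, and this call was lost with fry (adjusted p = 0.0689). The mean averages unlike strains. Against WT the respiratory medians were 0.46 in hpr1del, -0.46 in tho2del and -0.58 in sub2del, and the general stress medians 0.37, -0.305 and -0.56, so both gaps came mainly from hpr1del. Against tho2del alone, a comparison added after the data were seen, 4 respiratory genes were higher and 7 lower in sub2del (median -0.121, camera adjusted p = 0.985). General stress genes were 0 and 10 there (median -0.389, camera adjusted p = 0.196), and passed after quantile normalization (-0.292, 0.00706) and after array medians were subtracted (-0.276, 0.0120). Proteasome genes (12 of 33 higher and 1 lower, median 0.12, camera adjusted p = 3.99e-05) and Hsf1 targets (5 of 28 higher and 1 lower, median 0.13, camera adjusted p = 0.00660) were higher, with adjusted p = 0.889 for each with an estimated correlation, and the Hsf1 call was lost without sub2del replicate 1 (adjusted p = 0.0686) and with fry (0.175). Against tho2del alone these 2 lists passed (median 0.102, camera adjusted p = 0.000455, and 0.190, 0.000206), and not with an estimated correlation (adjusted p = 0.715 for each) or with fry (0.0814 and 0.127). Few members were called there, 2 of 33 proteasome genes higher and 0 lower (0 and 0 adjusted over the list alone), and 2 of 28 Hsf1 targets higher and 0 lower. Camera sets a list against the other genes, and the median log2 difference over all probe sets was -0.141. These calls therefore do not show that most members were higher in sub2del. Phosphate genes were also higher in sub2del than in tho2del (median 0.273, camera adjusted p = 0.000471) and pheromone-induced genes lower (-0.391, 0.0361). Both passed with fry (adjusted p = 0.000307 and 0.000301) and with camera in both other scalings, and not with an estimated correlation (adjusted p = 0.158 and 0.368). TDA4 was 3.61-fold higher in sub2del, ELO1, a fatty acid elongase gene, 2.99-fold, ARO10 2.62-fold, CHM7 2.57-fold and PBP2 2.46-fold. OYE3 was 5.46-fold lower, CWP1 4.89-fold, CHA1 4.23-fold, YER053C-A 3.70-fold, and RPS22B, an intron-containing gene of a ribosomal protein, 3.89-fold (2357 ± 23.4 in sub2del, n = 2, and 9103 ± 697 in the others, n = 5).

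In this comparison 1820 of 4332 probe sets passed, 518 higher and 1302 lower. The share of higher calls was 28.5%, 43.1% after quantile normalization and 49.2% after subtracting array medians. Without sub2del replicate 1 or 2 there were 1160 and 968 calls. With the empty-cell block 1659 passed, and 13 lists in place of 4.

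The comparison of tho2del with hpr1del asks whether the 2 THO subunits differ. Its list tests were added after the data were seen. Respiratory chain genes were lower in tho2del, with 43 of 48 falling and 0 rising (43 and 0 adjusted over the list alone; median -0.86, camera adjusted p = 1.16e-17, and adjusted p = 0.651 with an estimated correlation). The log2 difference of RIP1 was -1.94 ± 0.09 and that of COX5A -1.83 ± 0.11, and CYC1, cytochrome c, was 7.09-fold lower (9012 ± 78.9 in hpr1del, n = 3, and 1266 ± 220 in tho2del, n = 2). Phosphate genes were lower, 12 of 15 against 0 (12 and 0 adjusted over the list alone; median -0.91, camera adjusted p = 2.30e-05, and adjusted p = 0.0764 with an estimated correlation), PHO84 13.4-fold and PHO5, an acid phosphatase gene, 12.4-fold. Ribosome biogenesis genes were higher, 31 of 76 against 2 (31 and 3 adjusted over the list alone; median 0.23, camera adjusted p = 2.63e-07, and adjusted p = 0.651 with an estimated correlation), SSF1 by 1.21 ± 0.12. General stress (median -0.63, camera adjusted p = 1.48e-05), ergosterol (-0.67, 0.000101), purine (-0.50, 0.000101) and amino acid genes (-0.29, 0.00130) were lower, and G2/M genes (0.19, 0.00261) and meiosis genes (0.41, 0.00173) higher, with adjusted p between 0.651 and 0.719 with an estimated correlation. The general stress call was lost with fry (adjusted p = 0.0549). The meiosis median was -0.04 after quantile normalization (adjusted p = 0.132), and its call was also lost without tho2del replicate 1 (0.0688) and with the empty-cell block (0.356). SPS4 read 510 ± 28 in tho2del and 12.3 ± 2.71 in hpr1del, under the offset, so no fold is given. YKR104W was 8.54-fold higher in tho2del, RRG8 6.05-fold and FPK1, a protein kinase gene, 5.25-fold, CTR1 was 5.93-fold lower and YER053C-A 5.61-fold. IZH4 was 7.86-fold higher, a call lost without hpr1del replicate 1 or 2, without either tho2del array (log2 values from 2.59 to 3.10), with the replicate block (2.79, limma adjusted p = 0.0766) and with the empty-cell block (4.35, 0.0610).

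Between tho2del and hpr1del 1774 of 4601 probe sets passed, 724 higher and 1050 lower. Calls were 40.8% higher as deposited, 29.9% after quantile normalization and 50.2% after subtracting array medians. Without tho2del replicate 1 or 2 there were 1134 and 1051 calls, with the arrays of these strains alone 2757. These strains lie wholly in different levels of the empty-cell block, with which 1147 probe sets passed and the median of the respiratory list was -0.91 and that of the phosphate list -1.03. Other called lists moved more, amino acid genes to -0.588, G2/M genes to 0.367, ribosome biogenesis genes to 0.137 and general stress genes to -0.414, and each passed.

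**Figure D4:**
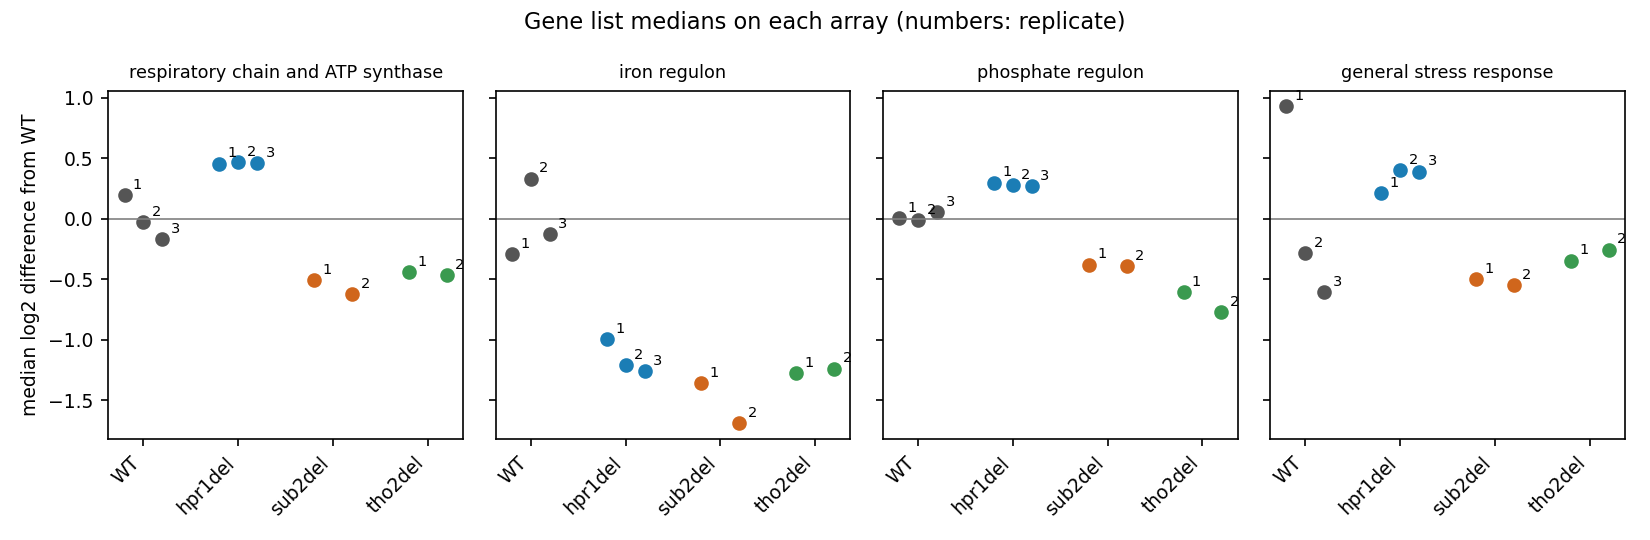
Median log2 difference of 4 gene lists on each array, by strain, with the replicate number at each point; mutant arrays are set against the mean of the 3 WT arrays and each WT array against the mean of the other WT arrays. The hpr1del arrays lie above 0 in the respiratory and phosphate lists and the sub2del and tho2del arrays below it, and WT replicate 1 stands at 0.93 in the general stress list.

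A relation of the changes to gene length was tested because THO mutants are known for effects on long transcripts. Across genes, which are not independent replicates, the rank correlation of the log2 change with coding length was -0.047 ± 0.0078 (SD, n = 3) in hpr1del, -0.035 ± 0.0018 (n = 2) in sub2del and -0.017 ± 0.018 (n = 2) in tho2del. It was -0.0037 ± 0.019 (n = 3) for each WT array against the others. After quantile normalization the values were -0.0543, -0.00936 and, with the direction turned, 0.00621, and in hpr1del it was -0.0924 without the dimmest 25% of probe sets. Genes higher in hpr1del had a median coding length of 1197 bases and those lower 1315.5 (permutation test, p = 0.0101, adjusted p = 0.0303 over the 3 mutants). In sub2del the medians were 1225.5 and 1299 (permutation p = 0.0962, adjusted p = 0.144), and in tho2del 1239 and 1236 (permutation p = 0.968). The log2 change also correlated with the WT level, at -0.129 in hpr1del, -0.156 in sub2del and -0.218 in tho2del, against a range from -0.115 to 0.102 in the WT arrays. Levels and changes share the WT arrays, and with the level taken from a WT array left out of the change the values lay between -0.0821 and -0.195.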

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

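The list tests of tho2del against hpr1del, the test of growth state for the respiratory genes and the empty-cell block were chosen only after the result was seen.

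The respiratory chain and ATP synthase list, which also holds citric acid cycle genes, stood out because the mutants differ in a test of the difference itself. Its median was -0.863 in tho2del against hpr1del and -0.595 in sub2del against the other mutants. The empty cells set tho2del, sub2del and WT replicate 2 apart from the other arrays, so a batch shared by them was tested as a cause. The list's median in WT replicate 2 relative to WT replicates 1 and 3 was -0.028, a share of 0.0328 of the change between the mutants. A share under 0.5 had been set beforehand as evidence against the batch, but it rests on WT replicate 2, the 1 WT array on that side, so the batch cannot be told apart from a difference between the mutants. A growth state of hpr1del nearer to stationary phase may also raise such genes. The stationary phase list gave a share of 0.0805, but its members went both ways (median -0.0688, SE 0.188, 22 genes), so this explanation cannot be told apart either. These list calls were lost with an estimated correlation (adjusted p = 0.651 and 0.889). A difference between loss of Hpr1 and loss of Tho2 or Sub2 stays open beside them, as a hypothesis.

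Iron regulon genes fell in all 3 mutants, a call lost with an estimated correlation (adjusted p = 0.474 in hpr1del, 0.631 in sub2del and 0.409 in tho2del). Raised values in 1 or 2 WT arrays were tested as a cause, and the tables argue against it: the lowest of the 3 WT medians lay 0.797 above the highest of the 7 mutant medians, with an SD of 0.214 between WT arrays. A state of all 3 WT cultures, such as less iron in their medium, could give the same fall, and cannot be told apart from a shared effect of the deletions because no other WT cultures were measured. Between mutants the list did not pass (smaller adjusted p = 0.247), although it did with the empty-cell block (adjusted p = 0.0134 for sub2del against the other mutants and 0.000888 for tho2del against hpr1del).

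Genes that rose in the mutants might be transcribed by read-through from an upstream gene on the same strand, in which case genes with such a neighbour should be over-represented. The opposite was measured: the difference in the share was -7.81 points in tho2del (42.6% of 1120 raised genes against 50.4% of 3409 others, permutation p = 2e-05, adjusted p = 6e-05). In sub2del it was -7.08 points (permutation p = 8e-05, adjusted p = 0.00012), and in hpr1del -1.8 points (permutation p = 0.271). The others include lowered genes, whose share was 51.3% in tho2del, 52.5% in sub2del and 49.9% in hpr1del. Against genes not called the gap was smaller and not tested, with the same direction. Raised genes and genes not called stood at 42.6% and 49.7% in tho2del, 43% and 47.6% in sub2del, and 46.8% and 48% in hpr1del. Read-through as the common cause of the rises is thereby argued against. Neighbouring genes are not independent, so the p-values are too small by an unknown amount.

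General stress genes also stood out for a tested difference between mutants, with medians of -0.631 in tho2del against hpr1del and -0.698 in sub2del against the other mutants. Both calls were lost with an estimated correlation (adjusted p = 0.696 and 0.889) and with fry (0.0549 and 0.0689). Phosphate regulon genes stood out for the same reason at -0.908 in tho2del against hpr1del, a call lost with an estimated correlation (adjusted p = 0.0764). Among probe sets with no gene name, which the comparisons leave out, 101 of 213 passed in hpr1del, 113 of 169 in sub2del and 98 of 176 in tho2del.

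Other splits of the arrays were counted for the 2 comparisons with at least 3 arrays a side. For hpr1del against WT, on 5051 probe sets with 6 values, the real split called 2037 and the highest of the others 0, with 1 of 10 splits reaching the real count, too few splits for a share under 0.05. For the 7 mutant arrays against WT, on 4137 probe sets, the real split called 1400 and the highest of the others 609. Of 100 drawn splits, the real one among them, 1 reached the real count. Arrays of a strain resemble each other and are not freely exchangeable, so the count shows only that the WT arrays stood apart as a group. It cannot tell an effect of the deletions from a difference between cultures or batches. The split with 609 set both sub2del arrays and tho2del replicate 2 against the rest.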

How the results depend on the processing

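The alternatives chosen only after the result was seen were the empty-cell block, at least 1 value per strain, only probe sets with 10 values and log2 with no offset, and for tho2del against hpr1del all list tests, with their alternatives. Of 300 counts of called probe sets, shared calls and called lists under the alternatives, 257 lay within 1.5 times the reported one. The correlations and the relations to coding length and WT level are not among them. The falls of HPR1, THO2 and SUB2 in their own strains kept direction and call under every alternative run, from -1.21 to -1.52, -2.88 to -3.64 and -6.69 to -7.45. Of the named genes, 333 of 339 results kept direction and call after quantile normalization, 329 of 339 after subtracting array medians and 306 of 318 with the empty-cell block. Most of these genes were named for large changes or low p-values in the same data, so these shares do not extend to all calls. Alternatives for the relation to GC content were not run, as that relation was not computed. With 1 array of a strain left out, a lone sub2del or tho2del array was assumed to vary like the other strains.

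Fewer probe sets pass a stricter threshold by its construction. At an adjusted p under 0.01 there were 1625 in hpr1del, 1021 in sub2del against the other mutants and 1038 in tho2del against hpr1del. At 1.5-fold or more there were 1105, 1689 and 1429 in hpr1del, sub2del and tho2del against WT, 1132 for the mean of the mutants, 625 in sub2del against the other mutants and 711 in tho2del against hpr1del, and at 2-fold or more 380, 786, 604, 410, 140 and 217. Calls shared at 1.5-fold or more were 568 for hpr1del and sub2del, 587 for hpr1del and tho2del, 1052 for sub2del and tho2del and 498 for all 3. Array weights gave 4149 calls in hpr1del and 2759 in tho2del against hpr1del. The latter comparison had 2757 with only the arrays compared, a fit that leaves out the spread of the more variable WT arrays. With the empty-cell block it had 1147. The cause of the other shifts was not tested. Leaving out 1 array gave 968 to 2402 calls in sub2del against the other mutants and 1051 to 2411 in tho2del against hpr1del, the lowest with 1 array left in a strain.

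The labels' replicate numbers did not pair the arrays, since deviations of arrays with the same number correlated between -0.215 and 0.0902. With a replicate block, 2177, 2597 and 2339 probe sets passed in hpr1del, sub2del and tho2del against WT, 2459 for the mean of the mutants, 1475 in sub2del against the other mutants and 1373 in tho2del against hpr1del.

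With an estimated correlation, camera called 0 lists in each comparison. The rotation test fry, which does not set a list against other genes, called 22 lists in sub2del, 13 in sub2del against the other mutants and 16 in tho2del against hpr1del on balance of direction. For change in either direction it called 31 in each mutant and 30 in both comparisons between mutants. The meiosis list of hpr1del, with a median of 0.255, reversed to a downward balance with fry, which used probe sets with 10 values (adjusted p = 0.287), and SMK1, a meiotic kinase gene, to -0.118 in tho2del against hpr1del after quantile normalization; the cause was not tested. In sub2del against the other mutants, 7 lists passed after quantile normalization, 13 with the empty-cell block and 3 to 7 with 1 array left out; the cause was not tested.

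With the empty-cell block fold changes correlated at 0.585 for hpr1del and sub2del, 0.651 for hpr1del and tho2del and 0.882 for sub2del and tho2del. The value for hpr1del and tho2del was 0.733 after quantile normalization and 0.741 without the dimmest 25% of probe sets. With 1 array left out the values ran from 0.633 to 0.658, 0.711 to 0.725 and 0.859 to 0.871.

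The relation to coding length in tho2del reversed to 0.00621 after quantile normalization. In hpr1del it was -0.0924 without the dimmest 25% and -0.0598 within strata of the WT level. In sub2del it was -0.0288 without ribosomal protein genes, -0.04 without the dimmest 25%, -0.0392 within strata, -0.00936 after quantile normalization and -0.0395 to -0.0306 with 1 array left out. The relation to the WT level was -0.247, -0.221 and -0.258 in hpr1del, sub2del and tho2del without the dimmest 25% and -0.163, -0.15 and -0.0989 after quantile normalization. It was -0.172 in sub2del and -0.232 in tho2del without ribosomal protein genes, and -0.165 and -0.222 within strata of the coding length. With 1 array left out it ran from -0.17 to -0.103, -0.18 to -0.138 and -0.24 to -0.199. With the level from WT replicate 1 alone it was -0.0821, -0.124 and -0.173, from replicate 2 -0.14 in sub2del and -0.195 in tho2del, and from replicate 3 -0.089, -0.0953 and -0.158. The cause of these shifts was not tested.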

Other observations

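Several gene lists fixed with the others were not past the threshold of camera in any mutant against WT. Genes of cytosolic ribosomal proteins (128, 117 and 121 tested) had a median log2 change of -0.03 in hpr1del, -0.06 in sub2del and -0.00 in tho2del (camera adjusted p = 0.179, 0.700 and 0.628). The list passed in sub2del after array medians were subtracted (median 0.13, adjusted p = 0.0104) and, downward, in hpr1del with the empty-cell block (median -0.0476, adjusted p = 0.0254). Genes of Hsf1 targets and chaperones stood at 0.00, -0.06 and -0.14 (adjusted p = 0.885, 0.241 and 0.684), and those of nuclear RNA surveillance, which degrades faulty transcripts, at 0.06, -0.06 and 0.13 (adjusted p = 0.810, 0.673 and 0.369). Cell wall genes with internal repeats had medians of 0.00, -0.25 and -0.03 (adjusted p = 0.885, 0.835 and 0.684). Of the 20 measured in hpr1del, 6 rose and 7 fell.

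Glycolysis and fermentation genes had medians of -0.03, -0.12 and -0.06 (adjusted p = 0.389, 0.662 and 0.539), and histone genes of 0.07, -0.10 and -0.23 (adjusted p = 0.274, 0.904 and 0.544). The 5 genes specific to the opposite mating type, MATalpha, stood at 0.03, -0.25 and 0.13 (adjusted p = 0.885, 0.755 and 0.419). In sub2del camera, which compares the mean test statistic of a list with that of the other genes, placed the lists of ribosomal proteins, Hsf1 targets, RNA surveillance, internal repeats, histones and MATalpha genes upward although their medians lay below 0. A p above the threshold does not show that these genes were alike in the strains.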
